A study of Homo sapiens with 8 samples.

How the data were processed

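HepG2 cells were sampled after 48 h with 0 or 20 mM D-lactate. Of 8 samples, 6 were RNA-seq libraries, 3 per arm, and 2 were CUT&Tag libraries for D-lactylated histone H3, 1 per dose, which were not analysed here. Per the labels' protocols, RNA was extracted with Trizol, poly-A RNA was captured on beads, and cDNA was made with random primers. Whether the libraries keep strand is not stated, and neither is how strand was used in counting.

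The submitters' processing notes name CASAVA, fastp, featureCounts 1.5.0-p3, DESeq2 1.20.0 and the hg38 build for RNA-seq, and FastQC, Bowtie2, MACS2 and deepTools for CUT&Tag. The RNA-seq aligner and the annotation release are not given in the sources used here. The deposited table has 30387 rows, each with at least 2 reads over the 6 libraries. Its expression values are a signal that is never negative: read counts per gene divided by 1 size factor per library, as the values deposited by the authors show. In every library 100% of values are whole multiples of the smallest one (relative tolerance 1e-06), so whole reads can be recovered. In 20 mM replicates 1 and 2 that step lies close to 1 (size factors 0.999 and 1.00), so it is told from rounding only by the decimals of the values. The deposited log2 fold change is 0 mM over 20 mM by the authors' means and was turned round here. The deposited p-value and adjusted p-value are the authors' own, per the file headers, and 32 rows have no p. Their adjusted p is 1 in 14757 rows; the highest mean scaled count of such a row that has a p is 14.3, which is also the lowest mean of the remaining rows.

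Rows with no gene name, 763 in all, held 0.44 to 0.48% of the reads and stayed out of the main test. Gene identifiers had a symbol in a separate name table in 29344 of 29624 named rows, and 2423 symbols differed from those listed; current symbols are printed. Total reads per library were 31531631 to 35703568, and the 10 most abundant genes held 11.6 to 12.6% of them. Intervals for counting error are not given, since the spread between libraries sets the precision. No pair of libraries within an arm agreed within sampling noise, with a chi-square per degree of freedom of 4.83 to 17.2.

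The test was limma 3.58.1 with an intensity trend on log2(scaled count + 1), on R 4.3.3, two-sided, for the 16116 named genes with a mean of at least 10 scaled counts over the 6 libraries. Treatment was the only term, and a Benjamini-Hochberg adjusted p under 0.05 was a call. Fold changes on this scale understate the change of low genes. A count model was planned for raw counts; because the deposited values are scaled, it was run on recovered reads as an added alternative (edgeR 4.0.16 and DESeq2 1.42.0). It called 4109 genes with edgeR and 4168 with DESeq2. Gene lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 39 lists.

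The lists and the rule for named genes were fixed before the data were examined. The rule took the 12 largest and 12 smallest log2 fold changes among called protein-coding genes with arms that do not overlap and a mean of at least 100. It also took up to 4 called members with the smallest p from each list (the 2 most abundant where none was called), the 5 genes with the smallest p in each direction, and a fixed set of lactate genes, of which LDHD, HAGH, GLO1, LDHA and EP300 are reported. Of the 168 genes so chosen, 69 overlap another listed gene, and in 21 that gene's mean is above 10% of their own. Overlapping genes and some near-identical relatives are given as uncertain. Sequence similarity between genes was not measured, so other named genes with close relatives may share reads without being marked. Values of some genes that the rule or a list takes are not reported here.

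The scripts were tested on simulated counts for the 16116 genes in the 20 against 0 mM comparison, with 200 changed, 50 at each fold. Limma found 16% of genes changed 1.2-fold, 58% at 1.5-fold, 76% at 2-fold and 90% at 4-fold, and called 9 unchanged genes. Camera called 10 of 10 lists shifted by 0.4 and 1 of 10 unshifted lists. These lists were random and their genes were drawn independently. The simulation therefore does not show how camera behaves on lists whose genes vary together.

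The alternatives fixed in advance were upper-quartile rescaling, no filter, a filter of 10 CPM in 3 libraries, limma without the trend, pseudocounts of 0.5 and 5, the replicate number as a block, leaving out each library, and an adjusted p under 0.01. For lists they were an estimated correlation, fry, the block, rescaling and leaving out each library. The count models, TMM factors, the inclusion of unnamed rows and camera on the edgeR model were added after seeing the data. Figures were drawn with matplotlib 3.10.9 on Python 3.11.15.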

Results

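HepG2, an established human liver cancer cell line, was cultured for 48 h with 20 mM D-lactate or without it (0 mM). D-lactate is the mirror-image form of the L-lactate made in human glycolysis, and the series title names bacteria as its origin. The comparison asked which transcripts differ in liver cells exposed to it. Poly-A RNA-seq was done on 3 samples per arm. No library with L-lactate or another solute is among the samples. For every difference below, D-lactate itself therefore cannot be told apart from a solute load of 20 mM. CUT&Tag, which tags DNA beside an antibody-bound histone mark, was done for D-lactylated histone H3 with 1 library per dose and was not analysed here.

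The RNA-seq libraries held 31531631, 34267290 and 32218344 reads assigned to listed genes at 0 mM and 33541853, 33807929 and 35703568 at 20 mM. Between 24094 and 24871 genes per library had at least 1 read. Across genes, which are not independent replicates, Pearson's r of log2 values was 0.987 to 0.989 within an arm and 0.977 to 0.979 between arms. The first principal component held 47.0% of the variance and separated the arms. Values below are scaled read counts as mean ± SD over the 3 libraries of an arm, and fold changes are 20 mM over 0 mM on the log2(count + 1) scale with the standard error (SE). The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples.

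Transcripts that rose with D-lactate included SLC6A12 and SLC5A3, which import betaine and myo-inositol, the metallothionein MT2A, the aldo-keto reductase AKR1C1, the chaperone HSPA5 and HMGCS1 of cholesterol synthesis. Transcripts that fell included the glucose transporter SLC2A3, the hexokinase HK2, the asparagine synthetase ASNS, and AFP, a secreted liver protein. PLA2G2A, a secreted phospholipase, rose from 469.7 ± 73.0 to 4928 ± 112 scaled counts (log2 fold change 3.40 ± 0.09). IGFBP1, a liver-secreted binding protein of insulin-like growth factors, fell from 22112 ± 2869 to 2800.1 ± 746.5 (log2 fold change -3.01 ± 0.13). In limma's test with Benjamini-Hochberg adjustment, 4117 of 16116 tested genes (25.5%) had an adjusted p under 0.05, with 2224 higher and 1893 lower. At least a 2-fold change was seen in 629 of them, 313 higher and 316 lower, and the median absolute log2 fold change of called genes was 0.42. The arms did not overlap in 39.8% of tested genes, where chance gives 10%. Without limma's intensity trend the count was 2539, and with a filter of 10 CPM in 3 libraries the number changed at least 2-fold was 168. The authors' deposited table calls 4067 rows, and 3861 of its calls were shared with the 4117 here, all with the same sign.

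Among protein-coding genes with a mean of at least 100, the 12 largest rises included the cadherin CDH16, the complement gene C7 and ETNPPL, an enzyme that breaks down phosphoethanolamine. The pepsinogen gene PGC, among the 5 higher genes with the smallest p, rose from 6827 ± 552 to 29640.0 ± 1967 (log2 fold change 2.12 ± 0.06; limma adjusted p = 2.55e-12). ETNPPL had a log2 fold change of 3.25 ± 0.18, CDH16 of 2.60 ± 0.12 and C7 of 2.61 ± 0.13, and ODAM, also named for its p, had 2.11 ± 0.07. The fucosyltransferase FUT3 had the largest rise named (4.03 ± 0.21), from 26.6 ± 6.59 to 439.9 ± 21.5, and has near-identical relatives that can share its reads. SPN, ANXA13, HID1 and GLP2R rose by between 2.40 and 2.94. SLC7A10 (3.49 ± 0.16) overlaps LRP3, whose mean was 967% of its own, so its rise is uncertain. Of genes named here and below, ADH4, ASNS, TP53INP1, ACSS2, GLUD1 and CP overlap listed genes whose means were 11.1 to 22.1% of their own.

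Among the largest falls were MIXL1, a homeobox transcription factor, and ADH4, a liver alcohol dehydrogenase. MIXL1 went from 1794 ± 149 to 188.5 ± 38.8 (log2 fold change -3.26 ± 0.13; limma adjusted p = 4.92e-11), and ADH4 had -2.79 ± 0.14. TXNIP, a glucose-responsive inhibitor of thioredoxin, fell from 3051 ± 300 to 773.6 ± 101.4 (-1.98 ± 0.10). ERRFI1, a feedback inhibitor of the EGF receptor, had -1.71 ± 0.08, RUFY1 -2.25 ± 0.29 and TCIM -2.02 ± 0.12. TUBB1 (-2.32 ± 0.20) and SLC16A6 (-2.07 ± 0.20) are uncertain, since overlapping ATP5F1E and ARSG had means of 497% and 124% of theirs.

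**Figure D1:**
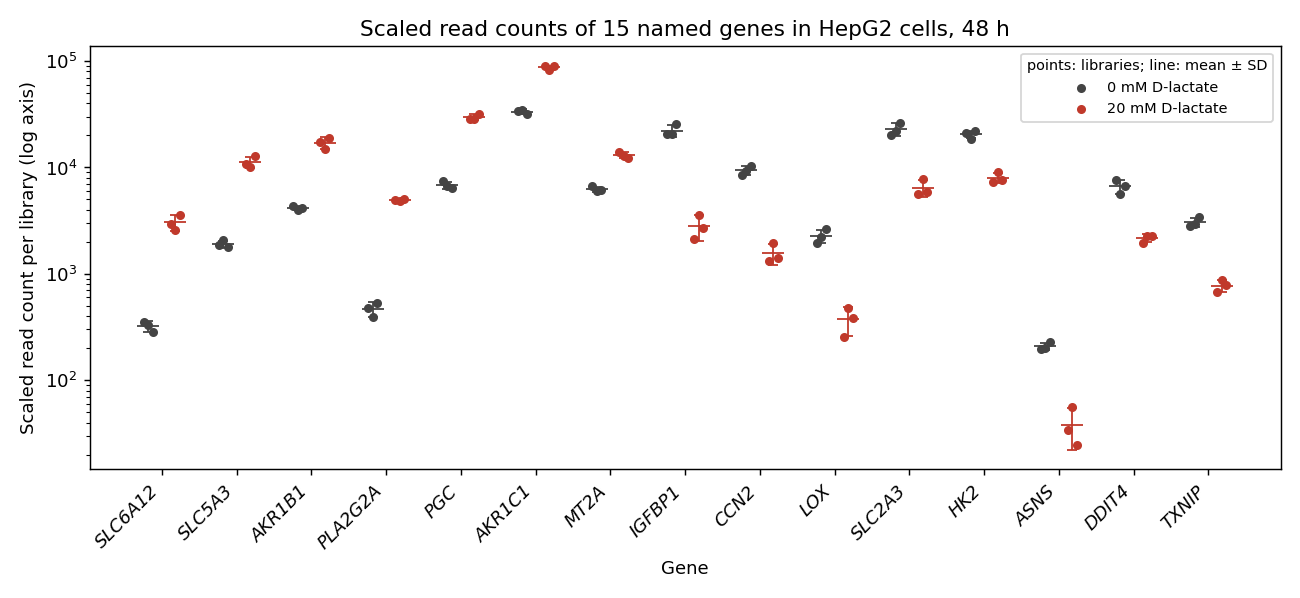
Scaled read counts (log axis) of 15 named genes in each of the 3 libraries per arm, grey for 0 mM and red for 20 mM D-lactate, with lines for mean ± SD. For each gene shown, all 3 libraries of one arm lie above all 3 of the other; PGC, for example, has a mean of 6827 without D-lactate and 29640.0 with it.

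Gene lists fixed before the data were examined were tested with camera, which compares a list with the other genes, at a preset inter-gene correlation of 0.01. Of 39 lists, 18 were called, 9 higher and 9 lower. With a correlation estimated from the data, camera called 0, while 11 lists had an unadjusted p under 0.05. The self-contained test fry, which asks only whether a list's genes move one way, called 24, including the 18 in the same direction. The other 6, given with fry's adjusted p below, were not called by camera. Counts of members "adjusted over the list alone" are given beside those over all genes tested. Members named because they moved against their list were chosen after their values were seen, unless the rule for named genes also takes them.

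In the osmotic stress list, 3 genes for osmolyte uptake or synthesis had the largest rises. The other 13 members had a median log2 fold change of -0.01, a value lowered by leaving out the largest rises. SLC6A12, the betaine transporter, rose from 322.8 ± 36.6 to 3058.5 ± 507.7 (log2 fold change 3.23 ± 0.11; limma adjusted p = 1.24e-11). SLC5A3, the myo-inositol transporter, rose from 1906 ± 140 to 11228 ± 1379 (2.55 ± 0.08), and AKR1B1, the aldose reductase that makes sorbitol, rose from 4162 ± 180 to 17100.0 ± 2039 (2.03 ± 0.07). On hg38, SLC6A12 (ENSG00000111181) lies on chromosome 12 from 190077 to 214570, and SLC5A3 (ENSG00000198743) on chromosome 21 from 34073570 to 34106262. SLC5A3 overlaps MRPS6, whose mean was 10.9% of its own. The osmotic stress list had 7 members higher, 3 lower and 6 not called of 16 (7 and 3 adjusted over the list alone). Its call, at camera adjusted p = 0.017, was lost at adjusted p = 0.17 with an estimated correlation. The 3 lower members were SLC6A8, the creatine transporter (-0.65 ± 0.08), SLC38A2, an amino acid transporter, and the kinase SGK1. The other higher members, which the rule for named genes does not take, were HSPA4L, TSC22D3, LRRC8D and SLC6A6.

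Metallothioneins are small proteins that bind zinc and copper, and their list also holds MTF1 and SLC30A1, which are not metallothioneins. Of its 9 tested members 7 were higher and 0 lower (7 and 0 adjusted over the list alone), with a median log2 fold change of 1.15. MT2A rose from 6252 ± 368 to 13032 ± 857 (1.06 ± 0.06), MT1G by 1.37 ± 0.08 and MT1F by 1.61 ± 0.09. Camera's adjusted p was 3.4e-10, against an adjusted p = 0.08 with an estimated correlation. The metallothionein genes are near-identical and can share reads, so single ones are uncertain. The NRF2 target list, genes of the oxidative stress response, had 12 higher, 3 lower and 8 not called of 23 (13 and 3 adjusted over the list alone), at camera adjusted p = 2.5e-06 and adjusted p = 0.17 with an estimated correlation. AKR1C1, a steroid-reducing aldo-keto reductase, rose from 33503 ± 1696 to 87266 ± 3513 (1.38 ± 0.05), AKR1C2 by 1.71 ± 0.05 and AKR1B10 by 1.53 ± 0.06. Reads of these 3 can also be split between close relatives. The 3 lower members were SLC7A11, the cystine transporter (-1.23 ± 0.06), the drug exporter ABCC3 and the heme oxygenase HMOX1.

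Hypoxia-inducible factor (HIF) targets fell, with 21 of 26 lower, 1 higher and 4 not called (24 lower and 1 higher adjusted over the list alone). The median log2 fold change was -0.66 and camera's adjusted p was 2.8e-16, with an adjusted p = 0.23 with an estimated correlation. LOX, which cross-links collagen, went from 2268 ± 337 to 372.8 ± 114.5 (-2.64 ± 0.17) and overlaps SRFBP1, whose mean was 31.1% of its own. BHLHE40, a transcription factor, had -1.07 ± 0.06, while P4HA2, a collagen prolyl hydroxylase, was the 1 higher member.

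Glycolysis genes followed the same direction, with 13 of 22 lower, 0 higher and 9 not called (15 and 0 adjusted over the list alone), a median of -0.35 and camera adjusted p = 1.3e-08. This became an adjusted p = 0.25 with an estimated correlation. The glucose transporter SLC2A3 fell from 22904 ± 3099 to 6451 ± 1206 (-1.83 ± 0.10; limma adjusted p = 3.17e-09). Its relative SLC2A14 was also tested, and whether they share reads was not checked. HK2, a hexokinase, had -1.36 ± 0.07, the liver glucose transporter SLC2A2 -1.55 ± 0.14, and PGK1 -0.57 ± 0.06. The gluconeogenesis and glycogen list had 8 lower, 3 higher and 5 not called of 16 (9 and 3 adjusted over the list alone), at camera adjusted p = 0.017 and adjusted p = 0.3 with an estimated correlation. G6PC1, which releases free glucose, had -2.75 ± 0.30 and FOXO1 -0.77 ± 0.07. The 3 higher members were pyruvate carboxylase PC (0.71 ± 0.06), CREB3L3 (1.30 ± 0.12) and the glycogen phosphorylase PYGB.

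Genes of the integrated stress response under the transcription factor ATF4, many for amino acid synthesis and import, fell in 22 of 27 cases, with 1 higher and 4 not called (22 and 1 adjusted over the list alone). The median was -0.64 and camera's adjusted p was 6.5e-16, with an adjusted p = 0.08 with an estimated correlation. ASNS, asparagine synthetase, went from 208.4 ± 17.0 to 38.1 ± 16.2 (-2.50 ± 0.26). DDIT4, an inhibitor of mTORC1, had -1.61 ± 0.09, MTHFD2 of the mitochondrial folate cycle -1.09 ± 0.06, and the serine synthesis enzyme PHGDH -0.91 ± 0.06. ALDH18A1, of proline synthesis, was the 1 higher member.

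The chaperone lists of the endoplasmic reticulum and the cytosol were both called higher. The endoplasmic reticulum unfolded protein list had 13 of 21 higher, 2 lower and 6 not called (14 and 2 adjusted over the list alone), at camera adjusted p = 8.1e-06 and adjusted p = 0.08 with an estimated correlation. HSPA5, the main chaperone there, rose from 49087 ± 1206 to 68201 ± 905 (0.47 ± 0.04), and DNAJC3 by 0.57 ± 0.06, while the sensor ERN1 and CREB3L2 were the 2 lower members. The cytosolic heat shock list had 11 of 16 higher, 1 lower and 4 not called (11 and 1 adjusted over the list alone), at camera adjusted p = 1.3e-06 and adjusted p = 0.1 with an estimated correlation. HSPH1 rose by 0.83 ± 0.05 and HSPA8 by 0.56 ± 0.05, and the mitochondrial chaperonin HSPD1 was the 1 lower member.

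Cholesterol synthesis and uptake genes rose in 16 of 24 cases, with 1 lower and 7 not called (16 and 1 adjusted over the list alone) and a median of 0.32. Camera's adjusted p was 1.1e-06, against an adjusted p = 0.08 with an estimated correlation. HMGCS1, an early enzyme of the mevalonate pathway, rose from 9278 ± 497 to 14252 ± 175 (0.62 ± 0.05), EBP by 0.53 ± 0.06 and IDI1 by 0.47 ± 0.07. The fatty acid and triglyceride synthesis list had 10 of 17 higher, 3 lower and 4 not called (10 and 3 adjusted over the list alone), at camera adjusted p = 0.017 and adjusted p = 0.25 with an estimated correlation. FASN, fatty acid synthase, rose by 0.40 ± 0.06, ACLY by 0.41 ± 0.05 and LPIN1 by 0.85 ± 0.08, while MID1IP1 (-0.47 ± 0.06), DGAT2 and MLXIPL were lower.

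The p53 target list had 16 of 24 higher, 1 lower and 7 not called (17 and 2 adjusted over the list alone), at camera adjusted p = 2.5e-06 and adjusted p = 0.08 with an estimated correlation. CDKN1A, the cell cycle inhibitor p21, rose from 3009 ± 172 to 4331 ± 120 (0.53 ± 0.06), TP53INP1 by 0.82 ± 0.07 and ZMAT3 by 0.57 ± 0.07, while BBC3, which promotes apoptosis, was lower. Interferon-stimulated genes had 10 of 22 higher, 2 lower and 10 not called (10 and 2 adjusted over the list alone), at camera adjusted p = 0.00051 and adjusted p = 0.12 with an estimated correlation. IFI6 rose from 200.6 ± 25.6 to 705.3 ± 3.26 (1.82 ± 0.12), IFIH1 by 0.72 ± 0.11 and OAS3 by 0.62 ± 0.06, while STAT2 and USP18 were the 2 lower members.

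Secreted hepatocyte proteins fell in 15 of 26 cases, with 3 higher and 8 not called (15 and 3 adjusted over the list alone), at camera adjusted p = 3.1e-06 and adjusted p = 0.08 with an estimated correlation. AFP, alpha-fetoprotein, went from 281550 ± 19430 to 179690 ± 5104 (-0.65 ± 0.05), TTR had -0.92 ± 0.06 and FGA -0.78 ± 0.04. The 3 higher members were albumin (ALB), HPX and APOE. Immediate early genes, induced within minutes by growth signals, had 10 of 22 lower, 1 higher and 11 not called (12 and 1 adjusted over the list alone), at camera adjusted p = 2.1e-05 and adjusted p = 0.14 with an estimated correlation. EGR1 had -1.28 ± 0.10, KLF10 -1.09 ± 0.09 and DUSP6 -0.91 ± 0.07, and JUND was the 1 higher member.

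The YAP and Wnt target list had 11 of 25 lower, 4 higher and 10 not called (12 and 4 adjusted over the list alone), at camera adjusted p = 0.0021 and adjusted p = 0.28 with an estimated correlation. CCN2, a matrix-associated growth factor listed as CTGF, went from 9403 ± 958 to 1556 ± 344 (-2.61 ± 0.11), ANKRD1 had -2.04 ± 0.15 and AJUBA -0.82 ± 0.05. The 4 higher members were AMOTL2 (1.10 ± 0.09), GLUL (0.41 ± 0.05), TCF7 and TBX3. Ribosomal protein genes had 12 of 49 lower, 0 higher and 37 not called (12 and 0 adjusted over the list alone), with a median of -0.11, RPL3 at -0.29 ± 0.05 and RPS12 at -0.29 ± 0.05. Camera's adjusted p was 1.1e-05, and the adjusted p = 0.3 with an estimated correlation. Their share of reads was 2.82 to 2.96% at 0 mM and 2.61 to 2.64% at 20 mM. The G2/M list had 6 of 31 lower, 1 higher (TOP2A) and 24 not called (6 and 1 adjusted over the list alone), with CCNB2 at -0.52 ± 0.07 and CDCA8 at -0.38 ± 0.07. Its camera adjusted p of 0.017 became an adjusted p = 0.49 with an estimated correlation, 0.11 without 0 mM replicate 2 and 0.052 without 20 mM replicate 3.

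**Figure D2:**
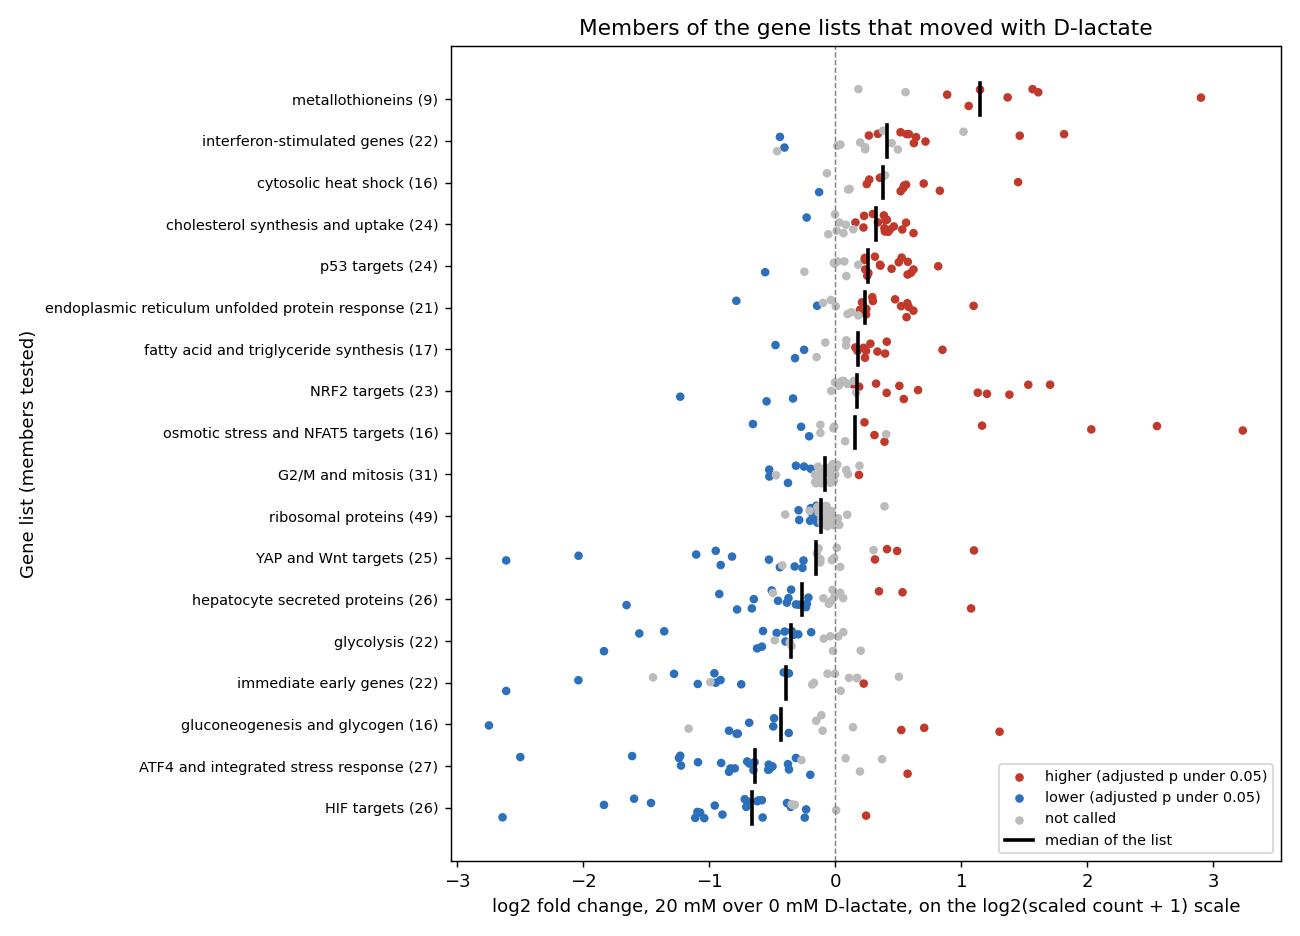
Log2 fold change (20 mM over 0 mM D-lactate) of each tested member of the 18 called gene lists, with points coloured by limma's call at an adjusted p of 0.05, black bars for list medians and the number of tested members in brackets. The metallothionein list has a median of 1.15, and HIF and ATF4 targets have medians of -0.66 and -0.64.

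Of the lactate genes fixed in advance, LDHD and GLO1 were higher and LDHA lower, while HAGH and EP300 did not pass the test. LDHD, the mitochondrial enzyme that oxidises D-lactate, went from 322.1 ± 48.1 to 447.1 ± 62.3 scaled counts (log2 fold change 0.47 ± 0.14; limma adjusted p = 0.0163). Its adjusted p was 0.097 without limma's trend, 0.074 without 20 mM replicate 1 and 0.094 without 20 mM replicate 3. GLO1, which with HAGH makes D-lactate from methylglyoxal, had 0.17 ± 0.06 (limma adjusted p = 0.0361). The GLO1 call was lost with the replicate number as a block (0.055), without limma's trend (0.17), and without 0 mM replicates 1 (0.083) or 3 (0.071) or 20 mM replicates 1 (0.15), 2 (0.12) or 3 (0.061). HAGH had -0.11 ± 0.09 (adjusted p = 0.39; it overlaps FAHD1 of similar abundance), and the acyltransferase EP300 0.04 ± 0.05 (adjusted p = 0.643). LDHA, an L-lactate dehydrogenase subunit, fell from 63803 ± 2975 to 52080 ± 2519 (-0.29 ± 0.05), and HCAR1, a lactate receptor, from 473.2 ± 70.3 to 243.4 ± 56.4 (-0.97 ± 0.16). The lactate handling list had 2 higher, 4 lower and 6 not called of 12 (2 and 4 adjusted over the list alone; camera adjusted p = 0.34). Fry called it lower (adjusted p = 0.0098). Lysine acylation writers and erasers had 3 higher, 5 lower and 14 not called of 22 (3 and 5 adjusted over the list alone; camera adjusted p = 0.91). In it ACSS2, which makes acetyl-CoA from acetate, rose by 0.57 ± 0.06, and the deacylases SIRT5 and SIRT1 had -0.42 ± 0.09 and -0.33 ± 0.08.

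Camera called no list of mitochondrial energy genes. The citric acid cycle list had 5 higher and 2 lower of 30 (5 and 2 adjusted over the list alone; camera adjusted p = 0.67), with the phosphatase PDP2 at 0.75 ± 0.07 and the kinase PDK1 at -0.96 ± 0.09. Nuclear-encoded oxidative phosphorylation had 1 higher and 4 lower of 38 (1 and 3 adjusted over the list alone; camera adjusted p = 0.42), and mitochondrially encoded genes 3 higher and 0 lower of 15 (3 and 0 adjusted over the list alone; camera adjusted p = 0.18). Fatty acid oxidation and PPARA targets had 6 higher and 9 lower of 25 (6 and 12 adjusted over the list alone; camera adjusted p = 0.1; fry called it lower at adjusted p = 0.016), with FABP1 at -1.54 ± 0.08 and ACSL1 at 0.82 ± 0.07.

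Other liver lists had members called in both directions and were not called by camera. Bile acid and xenobiotic genes had 7 higher and 3 lower of 18 (7 and 4 adjusted over the list alone; camera adjusted p = 0.17; fry called it higher at adjusted p = 0.00026), with CYP1A1 at 1.78 ± 0.12 and CYP3A5 at 1.90 ± 0.11. The urea cycle and amino acid catabolism list had 8 higher and 7 lower of 23 (8 and 7 adjusted over the list alone; camera adjusted p = 0.85; fry called it higher at adjusted p = 0.0052), with GLUD1 at -0.69 ± 0.05. Acute phase genes had 5 higher and 5 lower of 13 (5 and 5 adjusted over the list alone; camera adjusted p = 0.91), with ceruloplasmin CP at -1.64 ± 0.10 and A2M at 0.54 ± 0.04. Complement and coagulation genes had 5 higher and 8 lower of 23 (5 and 10 adjusted over the list alone; camera adjusted p = 0.38), with C5 at -1.18 ± 0.07 and C6 at 1.75 ± 0.18. Hepatocyte transcription factors had 5 higher and 3 lower of 21 (5 and 3 adjusted over the list alone; camera adjusted p = 0.91), with CEBPB at -0.83 ± 0.06. Iron genes had 8 higher and 5 lower of 18 (9 and 5 adjusted over the list alone; camera adjusted p = 0.17; fry called it higher at adjusted p = 0.0021), with STEAP3 at 0.90 ± 0.06 and the transferrin receptor TFRC at -0.42 ± 0.06.

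Signalling, growth and matrix lists below were called by neither camera nor fry. NF-kB and inflammatory mediators had 2 higher and 4 lower of 15 (2 and 4 adjusted over the list alone; camera adjusted p = 0.38), with NFKBIA at 1.22 ± 0.06 and TNFAIP3 at -0.82 ± 0.08. TGF-beta, matrix and mesenchymal genes had 11 higher and 6 lower of 26 (12 and 6 adjusted over the list alone; camera adjusted p = 0.38), with the matrix protein SPARC at 1.64 ± 0.06 and THBS1 at -0.77 ± 0.06. The median log2 fold change of this list was 0.24 and its mean 0.1, so most members leaned upward without a call of the list. G1/S genes had 4 higher and 4 lower of 31 (4 and 4 adjusted over the list alone; camera adjusted p = 0.7), and replication-dependent histone genes 3 higher and 0 lower of 14 (3 and 0 adjusted over the list alone; camera adjusted p = 0.24). Ribosome biogenesis and MYC targets had 2 higher and 5 lower of 30 (2 and 5 adjusted over the list alone; camera adjusted p = 0.85), with NPM1 at -0.28 ± 0.04.

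Markers of other liver cell types were measured as a check on the makeup of the samples, and camera called none of their 4 lists. White blood cell and macrophage markers had 2 higher and 1 lower of 5 tested out of 14 (2 and 2 adjusted over the list alone; camera adjusted p = 0.91). Stellate cell and fibroblast markers had 0 higher and 2 lower of 5 out of 13 (1 and 2 adjusted over the list alone; camera adjusted p = 0.73). Endothelial markers had 2 higher and 0 lower of 7 out of 12 (2 and 0 adjusted over the list alone; camera adjusted p = 0.11; fry called it higher at adjusted p = 0.0052), with VWF rising from 36.6 ± 8.35 to 142.2 ± 5.54. Bile duct and progenitor markers had 2 higher and 2 lower of 8 out of 13 (2 and 3 adjusted over the list alone; camera adjusted p = 0.91), with SPP1 at 0.60 ± 0.04 and KRT19 at -0.67 ± 0.07. The mitochondrial share of reads was 6.13 to 6.75% at 0 mM and 6.56 to 6.74% at 20 mM.

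In some lists without a camera call the median, mean and camera's direction differed in sign. The bile acid list had a median of -0.04 but a mean of 0.23 and an upward direction, and white blood cell markers a median of -0.03, a mean of 0.14 and an upward direction. Acute phase genes had a median of 0.03, a mean of -0.12 and a downward direction, as did stellate cell markers (0.01 and -0.23). Bile duct markers had a median of 0.04, a mean of -0.02 and an upward direction. Ribosome biogenesis (-0.01 and 0.01) and lysine acylation genes (0.04 and 0) had a downward direction.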

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

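The tests of solute load, cycling cells, reads shared within gene families and NRF2 targets below were chosen after the result was seen, as was the test of unnamed rows.

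Rows without a gene name stood outside the comparisons above and were looked at because some carried a signal with D-lactate above the control level. Of 548 such rows with a mean of at least 10, 49 were higher with D-lactate and 47 lower, and 26 were at least 2-fold higher. Rows at least 2-fold lower were not counted. The main test called a larger share of named genes, 4117 of 16116.

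With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split was the 1 with 4117 called genes, 629 changed at least 2-fold and 18 lists. In the other splits limma called 0 genes (187 to 444 at an unadjusted p under 0.05). Camera with the preset correlation called 2 to 9 lists there. Each of those splits mixes 2 libraries of an arm with 1 of the other. Part of the treatment difference therefore stays in its contrast and in its spread, so these counts do not measure false calls.

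The rise of 7 osmotic list members, led by SLC5A3, SLC6A12 and AKR1B1, was set against 3 explanations. Scaling between libraries is argued against only for the scalings tried. The lowest log2 fold change of a called member under TMM or upper-quartile rescaling was 0.22. The median of all tested genes moved only from 0.002 to -0.001 with TMM and -0.012 with upper-quartile rescaling, so this check could hardly have failed. Reads of overlapping genes are also argued against, since these gained at most 6.4% of a member's rise. A solute load of 20 mM, as any osmotically active compound could give, and an effect of D-lactate itself cannot be told apart, because no library with another solute is among the samples. The 13 members other than those 3 had a median of -0.01, which does not decide it.

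The joint fall of HIF, glycolysis and ATF4 targets remained after a trend on gene length and expression was removed, where the median nearest to 0 of the 3 lists was -0.36. Under TMM or upper-quartile rescaling it was also -0.36, though both lie close to the scaling of the main test and other scalings were not tried. A change in the share of cycling cells that moves G1/S and G2/M genes together was not seen, with medians of 0.05 and -0.08. A shift between cycle phases would move these lists apart, and the check cannot exclude it. Camera at the preset correlation called the G2/M list lower (adjusted p = 0.017), but not with an estimated correlation (0.49). Without members shared with the other lists, 21 of 26 ATF4 genes, 17 of 21 HIF genes and 10 of 18 glycolysis genes were lower. As for the osmotic genes, solute load and D-lactate itself cannot be told apart as the source of this fall.

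The rise of the metallothionein and AKR1C families is not a shift of reads between members, since the lower log2 ratio of a family's summed reads was 1.16. Under TMM or upper-quartile rescaling, both close to the scaling of the main test, the lowest ratio was 1.14. Summed scaled counts went from 10399 to 23194 for metallothioneins and from 50611 to 130090 for AKR1C. A general NRF2 response may contribute and stays open: the 20 other NRF2 targets had a median of 0.14 (95% bootstrap interval 0.04 to 0.37), with 9 higher and 3 lower, which neither shows nor excludes it. The bounds for this reading were changed after the value was seen: under the first bound, a median below 0.5, a general response had been excluded as the whole account. Solute load and D-lactate itself cannot be told apart for these families either.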

How the results depend on the processing

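The edgeR, DESeq2, TMM and unnamed-row settings, and camera on the edgeR model, were chosen after seeing the data. Without limma's trend 2539 genes were called, 1334 higher and 1205 lower, and at an adjusted p under 0.01 there were 2621, with 1437 and 1184. Genes changed at least 2-fold numbered 168 with the filter of 10 CPM, 79 higher and 89 lower, against 629 in the main test. That filter tested 9069 genes against 16116 and called 3362 against 4117. The 2-fold count thus fell by a larger share than the genes tested or the calls. With an estimated correlation 0 lists were called. For the trend and the estimated correlation the cause was not tested. The other settings stayed within 1.5 times of the main counts: edgeR called 4109 genes (4029 shared), DESeq2 4168 (4020 shared), upper-quartile rescaling 4054, and the test with unnamed rows 3994 (3894 shared). Leaving out 1 library gave 2994 to 4443 genes, 552 to 636 changed at least 2-fold, and 17 to 18 lists. The calls rose to 4426 without 0 mM replicate 1 and to 4443 without 0 mM replicate 2. Without any other library they fell to between 2994 and 3227. Those replicates also differed most within an arm, with a chi-square per degree of freedom of 17.2.

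Replicate numbers did not pair the samples: same-numbered deviations correlated at -0.03, -0.01 and 0. With the replicate number as a block 3913 genes were called (3791 shared) and 18 lists, and of named genes only the GLO1 call was lost. All 168 named genes kept their call or lack of one under edgeR, DESeq2, TMM and upper-quartile rescaling. Without the trend 22 lost it, as did 27 of 1008 cases with a library left out, and no named gene changed sign with a call. Small changes can still be missed, since the simulated recovery was 16% at 1.2-fold. That simulation changed 200 of 16116 genes, while 25.5% were called in the data. The adjusted p is less strict where more genes change, so the simulated recovery does not carry over directly.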

Other observations

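All tests here were chosen after the data were seen, and genes named here were chosen after their values were seen. Sets of genes sharing a protein domain in the table's gene descriptions were tested with camera at the preset correlation: 8 of 226 sets were called. With an estimated correlation camera called 0, with 8 at an unadjusted p under 0.05 and a lowest adjusted p of 0.83. Laminin N-terminal domain genes, mostly chains of the basement membrane, had 6 of 11 higher and 0 lower, with a median log2 fold change of 0.42. Insulin-like growth factor binding domain genes had 5 of 10 lower and 0 higher, with a median of -0.45 and IGFBP1 and CCN2 among them. Sugar transporters had 6 of 15 lower and 0 higher (median -0.25), and aldo-keto reductases 7 of 15 higher and 1 lower (median 0.34). Thioredoxin domain genes had 10 of 25 higher and 0 lower, and Hsp70 genes 6 of 10 and 0. The von Willebrand type C domain set had 7 of 15 lower and 1 higher, and the thioredoxin-like set 6 of 12 higher and 0 lower. Several of these genes also sit in the fixed lists, so the sets are not separate evidence.

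Transcripts outside protein-coding genes leaned the other way from coding ones. Among antisense and lincRNA genes 66 were higher and 146 lower of 1727 tested, against 2106 higher and 1615 lower of 12451 protein-coding genes. The odds of a call being lower were 2.88 times those of coding genes (95% interval 2.13 to 3.95; Fisher's exact p = 4.7e-13, two-sided, with genes treated as independent, which they are not). Among genes with a mean of 10 to 50 scaled counts the odds ratio was 2.66 (1.42 to 5.09; Fisher's exact p = 0.0014). Over all tested genes the median log2 fold change was -0.17 for antisense and lincRNA genes and 0.02 for coding genes. With a mean of 10 to 50 scaled counts the medians were -0.16 and 0. Strand use in counting is not stated, so reads of an antisense gene and its partner cannot be separated.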
